A study of Homo sapiens with 6 samples.

How the data were processed

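Total RNA of cells labelled HCT116, an established human colorectal carcinoma line, was sequenced in 6 libraries, 3 from control cells (NC) and 3 from cells transfected with an antisense oligonucleotide (ASO) directed at SNORA67. An antisense oligonucleotide is a short single-stranded nucleic acid that pairs with an RNA and can lead to its degradation. The identity of the cells rests on the labels and was not tested. SNORA67 is a small nucleolar RNA of the H/ACA class, the class that guides pseudouridylation of other RNAs. The number and sequence of the oligonucleotides, the treatment of the control cells, the dose and the time of harvest are not given in the sources used here. Nothing in the labels states that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

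The submitters' processing notes name FastQC, STAR, StringTie, DESeq2 and the build hg38, without versions, roles or parameters. The deposited table holds estimated counts per gene for 19655 gene symbols, with no scaling to depth. The annotation release, the strand setting and the handling of reads that match several genes are not given in the sources used here, so overlapping genes on opposite strands and near-identical copies such as HSPA1A and HSPA1B are uncertain. Column totals of the deposited counts were 52540779, 53715905 and 50728524 in the NC libraries and 54905215, 49136502 and 50637893 in the ASO libraries. The most frequent value above 0 was 4 in every library, with 226 to 296 genes at 4 against 74 to 121 genes at 3. Counts derived from coverage pile up in this way when 1 sequenced fragment is worth about 4 counts, which would put the depth at 12.3 to 13.7 M fragments per library (M, 1e6). The smallest amount taken as detected was therefore 3 fragments, or 12 counts per library, a mean of 0.228 CPM (counts scaled to a library total of 1e6) in the NC libraries. Such limits cover counting error only. The values were whole numbers as deposited, so rounding them changed nothing.

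The deposited counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the group as its argument, at a minimum count of 10 and a minimum total count of 15, which left 14062 genes and removed 5593. Library sizes were scaled by the trimmed mean of M values (TMM), with factors of 0.978 to 1.02. ASO was compared with NC by the robust quasi-likelihood test of edgeR without a replicate block, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Levels are TMM-scaled CPM, given as mean ± SD over n = 3 libraries, and fold changes are those of the edgeR model. Genes at 0 in every NC library have no fitted fold change that could be quoted, and their fold is given as a lower bound against the 12-count limit per library.

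23 gene lists were tested with camera on log2 CPM at a prior count of 2, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. They were Wnt target genes, Wnt pathway components, mitosis, DNA replication, p53 targets, cytosolic ribosomal proteins, ribosome biogenesis and snoRNP factors, snoRNA host genes, translation initiation factors, interferon-stimulated genes, unfolded protein and integrated stress response, NF-kB targets, immediate early genes, cholesterol synthesis, hypoxia and glycolysis, epithelial genes, mesenchymal genes, apoptosis regulators, nuclear and mitochondrially encoded oxidative phosphorylation genes, replication-dependent histones, heat shock genes and markers of non-epithelial cells. Older symbols were resolved through the synonyms of the RefSeq gene table. A further list of snoRNA and scaRNA genes matched 0 genes of the table. The same lists were run with a correlation estimated for each list and with fry. With an estimated correlation, camera also rests its test on the few residual degrees of freedom of the libraries.

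Genes named in the text were chosen by a rule that took EIF4A1 and DLGAP5, the 10 largest rises and 10 largest falls by fitted fold change among changed genes at 1 CPM or more whose groups did not overlap, the 5 smallest p-values in each direction, up to 4 changed genes per list, and AXIN2, LGR5, MYC, CCND1, CDKN1A and MDM2. Neighbours of EIF4A1, upstream neighbours of named genes and the keratin, adhesion and mesenchymal genes given as levels are outside this rule and were chosen after values were seen. The edgeR and camera tests, the lists, this rule and the alternatives were fixed before the data were examined. Alternatives were other scalings (RLE, upper quartile, none), other filters (none, a mean of 10 counts), DESeq2 1.42.0, limma-voom, removal of the mitochondrially encoded genes, a replicate block and leaving out each library. Restricting the table to genes with a symbol moved nothing, since every entry has one. Division of the counts by 4 was added after the data were seen.

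Tested on simulated data built from these libraries, with 200 genes changed among 13043 tested, the edgeR step recovered 14.9% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 84.8% of those changed 4-fold, and 12 of its calls, 9.68%, were false. The shifted list was called and 0 of the 22 other lists were. Genes were drawn independently, so the check cannot show how the list test behaves when genes of a list are correlated. It also changed far fewer genes than the 6464 called in these libraries, in equal numbers up and down. Replicate libraries differed by more than sampling noise, with a chi-square of 11.1 to 30.1 per gene for each pair of the same group, so none was treated as a duplicate.

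Strand, gene span, summed exon length and the GC content of the longest transcript came from GENCODE release 29 on GRCh38, matched by symbol and position for 95.7% of the genes. Trends and random lists were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.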

Results

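Gene expression was measured by RNA sequencing in cells labelled HCT116, 3 libraries of control cells (NC) and 3 of cells given an antisense oligonucleotide against SNORA67 (ASO). Column totals of the estimated counts ran from 50728524 to 53715905 in NC and from 49136502 to 54905215 in ASO. The series addresses how SNORA67 acts in colorectal cancer cells, and its title names DLGAP5 and Wnt signalling. The only comparison its design implies is ASO against NC.

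SNORA67 lies on chromosome 17 at 7577955 to 7578091 of GRCh38, on the plus strand, between exons 9 and 10 of the 11-exon transcript EIF4A1-201 and thus in an intron of its host gene EIF4A1. SNORA67, SNORA48 and SNORD10, all small RNAs of the EIF4A1 introns, were not analysed here, so the knockdown itself was not checked. EIF4A1, the RNA helicase of the cap-binding translation initiation complex (chromosome 17, 7572825 to 7579006), was lower in all 3 ASO libraries, at 617 ± 46.3 CPM against 1544 ± 55.3 CPM in NC (SD, n = 3 each). The difference of 2.5-fold had an adjusted p of 1.49e-05 in edgeR, the smallest among the genes that fell. The joint SENP3-EIF4A1 model has no values in the table. Its neighbours did not follow it. SENP3, upstream on the same strand, stood at 163 ± 6.19 CPM against 161 ± 6.24 CPM (edgeR adjusted p = 0.895). CD68, a macrophage-associated lysosomal protein gene that starts 485 bases beyond the end of EIF4A1 on the same strand, rose 4.17-fold to 93.1 ± 12.4 CPM (edgeR adjusted p = 1.43e-05). SOX15, on the minus strand within the span of MPDU1, rose 12.6-fold from 1.83 ± 0.58 CPM (edgeR adjusted p = 3.49e-05), and without stranded counting its reads and those of MPDU1 cannot be separated.

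**Figure D1:**
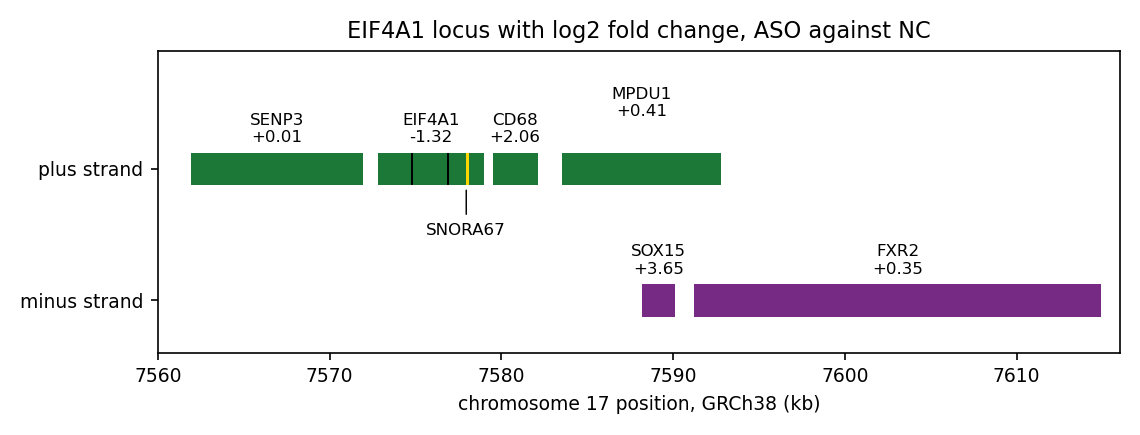
Map of the EIF4A1 locus on chromosome 17 (horizontal axis, GRCh38 position in kb) with genes of the plus strand above and of the minus strand below, SNORA67 in yellow, SNORA48 and SNORD10 in black, and the log2 fold change of ASO against NC printed over each gene. EIF4A1 stands at -1.32, between SENP3 at 0.01 and CD68 at 2.06.

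DLGAP5, a spindle-associated protein of mitotic cells (chromosome 14, 55148112 to 55191608), was lower in the 3 ASO libraries, at 11 ± 4.67 CPM against 35.6 ± 4.14 CPM in NC. The fall was 3.23-fold (edgeR adjusted p = 0.00243). The study named this gene, so its direction is not an independent choice. It fell together with other genes of mitosis. Of 44 mitosis genes tested, 25 fell, 2 rose and 17 did not pass the edgeR threshold, and the counts were the same when adjusted over the list alone. CENPE, a kinetochore motor, fell 4.30-fold, HMMR 3.81-fold, CENPF 2.78-fold and KIF20A 1.79-fold. The 2 that rose, named after their values were seen, were AURKB and CDCA8 of the chromosomal passenger complex, by 0.50 and 0.35 on the log2 scale. The list's median log2 fold change was -0.56, and camera called it lower (adjusted p = 8.41e-06, but adjusted p = 0.168 with an estimated correlation). Mitosis genes had a median GC content of 43.2% against 48.7% for the genes at 1 CPM or more on average in NC. Fold changes rose with GC content across those genes. DNA replication genes were made up of 15 lower and 7 higher of 45 and a median of -0.22. MCM4 fell 1.51-fold, TYMS 1.43-fold and PRIM1 2.04-fold. Camera called this list lower (adjusted p = 0.0144, but adjusted p = 0.094 with an estimated correlation), and adjusted over the list alone the counts were unchanged at 15 and 7. After trends with GC content and length were removed, the medians were -0.21 for mitosis genes and -0.10 for DNA replication genes, at the 0.71 and 22.98 percentiles of random lists.

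Over all genes, 6464 of 14062 passed the edgeR threshold, 3772 higher and 2692 lower in ASO, which is 46.0% of those tested. At least 2-fold changes were made up of 2382 higher and 549 lower genes. The groups did not overlap for 57.6% of the genes, where chance gives 10%. The first principal component held 81.6% of the variance and parted the 2 groups. The count of lower genes depended on single libraries, being 1755 without NC replicate 1 and 1764 without ASO replicate 3, and the 549 lower genes became 874 without ASO replicate 2. More genes had any count in ASO (15452 to 15665 per library) than in NC (13934 to 13995), and 333 genes at 0 in every NC library reached 12 counts in every ASO library, against 4 the other way.

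Targets of NF-kB, the transcription factor of inflammatory signalling, rose most. All 24 members tested were higher in ASO, also when adjusted over the list alone and with DESeq2 and limma-voom, with a median log2 fold change of 3.55 (camera adjusted p = 1.68e-13, and adjusted p = 0.0357 with an estimated correlation). TNFAIP3, a feedback inhibitor of NF-kB, had the smallest p of all genes and rose 148-fold, from 3.91 ± 0.49 to 579 ± 18.6 CPM (edgeR adjusted p = 2.1e-07). IL6 rose 33.2-fold to 795 ± 15.1 CPM and CXCL2 19.9-fold to 187 ± 9.18 CPM, both encoding secreted inflammatory mediators. TNF went from 0.11 ± 0.03 CPM, below the detection limit of 0.228 CPM, to 55.2 ± 5.32 CPM. PTX3, an acute-phase pattern recognition protein gene, rose 44.8-fold, and IRAK2, a kinase of Toll-like and interleukin-1 receptor signalling, rose 15.2-fold. Interferon-stimulated genes did not move as a list, with 6 higher and 4 lower of 32, 5 and 4 adjusted over the list alone, and a median of -0.04 (camera adjusted p = 0.566). The mean of 0.03 had the opposite sign. STAT2 fell 1.61-fold, while ISG15 and ISG20 rose 2.03-fold and 4.47-fold.

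Immediate early genes, which respond first to growth factor and stress signals, rose as well. Of 31 tested, 30 were higher, also adjusted over the list alone, and 29 with limma-voom, with a median log2 fold change of 2.83 (camera adjusted p = 3.87e-13, and adjusted p = 0.0415 with an estimated correlation). EGR1 rose 8.51-fold to 2252 ± 62.3 CPM, IER3 9.26-fold to 1406 ± 109 CPM, FOSL1 42.7-fold to 428 ± 54.4 CPM and DUSP5, a phosphatase that acts on ERK, 26.0-fold to 164 ± 7.48 CPM. FOS, named after its values were seen, was the single member that did not pass, at a log2 fold change of 0.17 (edgeR adjusted p = 0.22). Replication-dependent histone genes rose in 35 of 46 members by edgeR and by DESeq2 and in 36 by limma-voom. They fell in 0 by each of these tools, with 0 lower at an unadjusted p under 0.05 as well. Adjusted over the list alone the counts were 35 and 0, and the median was 1.72 (camera adjusted p = 4.02e-11, and adjusted p = 0.0357 with an estimated correlation). H2BC6 rose 12.2-fold, H2BC21 4.58-fold, H2AC6 2.97-fold and H1-2 2.85-fold. These genes are a multigene family, so reads may be split between copies.

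**Figure D2:**
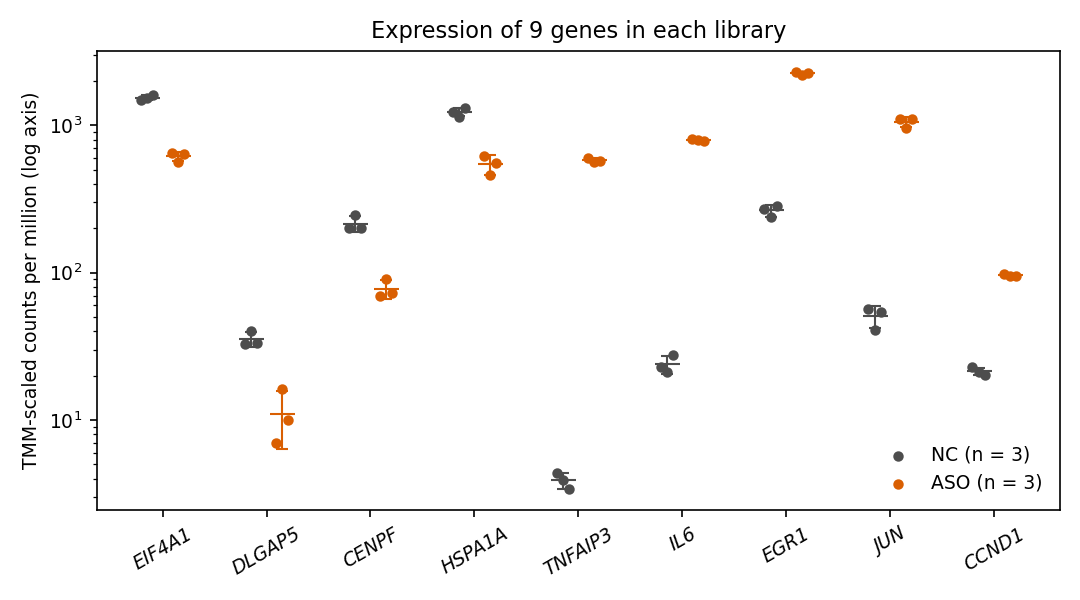
Expression of 9 genes in each library, in TMM-scaled CPM on a log axis, with NC in grey and ASO in orange (points, libraries; horizontal bars, means; error bars, SD; n = 3 each). No gene has overlapping groups, and TNFAIP3 goes from 3.91 CPM in NC to 579 CPM in ASO.

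Wnt target genes rose in 8 of 17 members tested and fell in 1, with a median log2 fold change of 0.78. Adjusted over the list alone, 9 were higher and 1 lower. The list held 28 genes, and the others did not pass the filter on low counts. Among these, LEF1, SP5 and ASCL2, named after their values were seen, had 0 counts in every library. JUN rose 20.9-fold to 1057 ± 82.7 CPM, DKK1, a secreted Wnt inhibitor, 6.48-fold, the cyclin D1 gene CCND1 4.47-fold to 95.7 ± 1.69 CPM, and RNF43, a ligase that removes Wnt receptors, 2.47-fold. JUN is also an immediate early gene, and it and MYC are in both lists. The member that fell, named after its values were seen, was PPARD (-0.49 on the log2 scale). Camera called the list higher (adjusted p = 0.00694, but adjusted p = 0.466 with an estimated correlation). AXIN2, a feedback target often read as a measure of Wnt activity, was near the detection limit in both groups, at 0.58 ± 0.30 CPM in NC and 0.18 ± 0.16 CPM in ASO (edgeR adjusted p = 0.203). LGR5, a Wnt-dependent stem cell receptor gene, had 0 counts in each NC library and 14, 3 and 0 counts in the ASO libraries, with 1 of them over the limit of 12. MYC was at 191 ± 33.3 CPM against 80.8 ± 49.3 CPM, 2.36-fold higher (edgeR adjusted p = 0.0289). Without NC replicate 3 the rise was 3.6-fold and the call held. It held with none of the other 5 libraries left out, where the edgeR adjusted p ran from 0.0692 to 0.124. Nor did it hold with no filter on low counts (edgeR adjusted p = 0.072). Wnt pathway components were not called (camera adjusted p = 0.651, median 0.10), with 11 higher and 4 lower of 46, or 8 and 4 adjusted over the list alone. CSNK1E, PORCN and BCL9L rose 2.35-fold, 2.19-fold and 2.00-fold, and WLS fell 1.69-fold.

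Heat shock genes fell in 11 of 19 members by edgeR and in 13 by DESeq2 and by limma-voom. They rose in 0 by each of these tools, with 0 higher at an unadjusted p under 0.05 as well. Adjusted over the list alone 13 fell, with a median log2 fold change of -0.84 (camera adjusted p = 3.37e-05, and adjusted p = 0.0415 with an estimated correlation). HSPA1A and HSPA1B, near-identical copies, fell 2.27-fold and 2.28-fold, and HSP90AB1 fell 1.55-fold from 5290 ± 316 CPM. AHSA1, an activator of Hsp90 outside the list, fell 1.93-fold. Nuclear genes of oxidative phosphorylation fell in 30 of 68 members by edgeR and in 31 by DESeq2 and by limma-voom. They rose in 0 by each of these tools, with 0 higher at an unadjusted p under 0.05 in edgeR and limma-voom and 1 in DESeq2. Adjusted over the list alone 28 fell, with a median of -0.27 (camera adjusted p = 8.14e-07, and adjusted p = 0.0357 with an estimated correlation). COX7C fell 1.52-fold and ATP5F1A 1.44-fold. Mitochondrially encoded genes fell in 5 of 13 and rose in 1, also adjusted over the list alone, with a median of -0.61. MT-ND5 fell 2.96-fold and MT-CO1 1.71-fold, and the member that rose, named after its values were seen, was MT-ND1 (0.18 on the log2 scale). Their share of counts was 2.80% to 3.31% in NC and 1.89% to 2.66% in ASO. The camera call (adjusted p = 0.0298, but adjusted p = 0.555 with an estimated correlation) ended without NC replicate 2 (adjusted p = 0.0559) and without ASO replicate 1 (adjusted p = 0.089). Translation initiation factor genes, EIF4A1 included, fell in 14 of 39 and rose in 2, 12 and 2 adjusted over the list alone, with a median of -0.22 (camera adjusted p = 0.00158, but adjusted p = 0.0589 with an estimated correlation). EIF5B fell 2.39-fold, while EIF1 and EIF2B2 rose 1.51-fold and 1.59-fold. Cytosolic ribosomal protein genes fell in 23 of 79 and rose in 5, 16 and 3 adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.00158, but adjusted p = 0.3 with an estimated correlation). RPS13 and RPL5 both fell 1.5-fold, and RPL28 and RPS29 rose 1.61-fold and 1.69-fold. After trends with GC content and length were removed, the medians were -0.63 for heat shock, -0.14 for nuclear and -0.29 for mitochondrially encoded oxidative phosphorylation, -0.20 for initiation factor and -0.08 for ribosomal protein genes, the last at the 55.3 percentile of random lists.

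Cholesterol synthesis genes fell in 12 of 24 members and rose in 1, 13 and 1 adjusted over the list alone, with a median of -0.42 (camera adjusted p = 0.00103, but adjusted p = 0.094 with an estimated correlation). TM7SF2, a sterol reductase gene, was the member that rose, by 3.42-fold. Hypoxia and glycolysis genes rose in 15 of 33 and fell in 3, also adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.021, but adjusted p = 0.357 with an estimated correlation). ANGPTL4 rose 29.2-fold, PFKFB4 10.3-fold and NDRG1 2.58-fold. The 3 that fell, named after their values were seen, were the glycolytic enzyme genes TPI1, GPI and HK1.

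Several lists moved in both directions and were not called by camera with the preset correlation. Unfolded protein and integrated stress response genes split into 15 higher and 9 lower of 33, 15 and 10 adjusted over the list alone (camera adjusted p = 0.374, median 0.20). PPP1R15A, ATF3 and CHAC1 rose 14.5-fold, 12.6-fold and 27.7-fold. The chaperone genes HSP90B1 and HSPA5, named after their values were seen, fell 2.13-fold and 1.49-fold. Targets of p53 split into 9 higher and 6 lower of 30, 9 and 8 adjusted over the list alone, with a mean of 0.52, or 0.30 with the member at 0 in NC at its lower bound, and a median of -0.10 (camera adjusted p = 0.995). GDF15 rose 12-fold, SESN2, also on the stress response list, 5.67-fold and PLK3 6.84-fold, while CCNG1, named after its values were seen, fell 2.88-fold. CDKN1A was at 152 ± 103 CPM against 104 ± 55.5 CPM (edgeR adjusted p = 0.45), with a log2 fold change of -0.18 without ASO replicate 2, and MDM2 at 51.0 ± 9.86 CPM against 62.3 ± 10.1 CPM (edgeR adjusted p = 0.214). Apoptosis regulators rose in 13 of 36 and fell in 3, also adjusted over the list alone (camera adjusted p = 0.133, median 0.27), and members known to restrain and to promote cell death rose. CFLAR, MCL1 and BCL2L1, which restrain it, rose 6.03-fold, 2.85-fold and 2.72-fold, and the death receptor gene TNFRSF10B, also a p53 target, and PMAIP1, which promotes it, rose 2.15-fold and 3.44-fold. Those that fell included CYCS and CASP6, named with PMAIP1 after their values were seen. Ribosome biogenesis and snoRNP genes split into 8 higher and 10 lower of 67, 6 and 9 adjusted over the list alone (camera adjusted p = 0.17, median -0.06). NPM1 and NCL fell 1.68-fold and 1.52-fold, while RRP12 and TAF1D rose 1.46-fold and 1.81-fold. Of 31 other snoRNA host genes listed, 13 are among the gene symbols of the deposited counts. They split into 2 higher, TNPO2 and TAF1D, and 2 lower, NCL and EEF1B2, also adjusted over the list alone (camera adjusted p = 0.649). Their median was 0.04, and the mean of 0.01 fell below 0 with upper-quartile scaling and with library size alone.

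**Figure D3:**
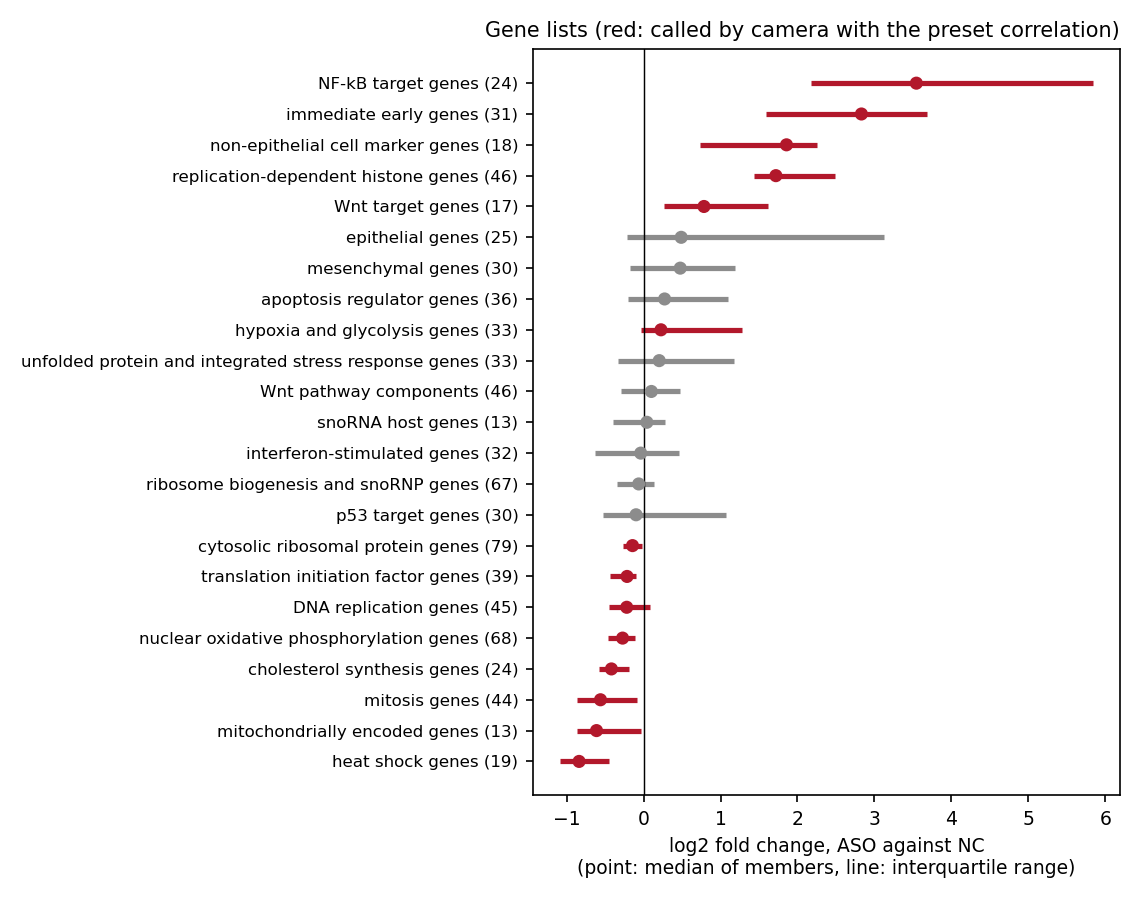
Median log2 fold change of ASO against NC (points) and interquartile range (lines) over the tested members of each of 23 gene lists, with the number of members in parentheses and lists called by camera with the preset correlation in red. NF-kB targets stand highest at 3.55 and heat shock genes lowest at -0.84.

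Many genes of the epithelial list were low in all 6 libraries, and whether these are cells of the labelled line was not tested. Of the 32 genes on the list, 7 reached 10 CPM on average in NC and 18 lay under 1 CPM. Keratin genes KRT8 and KRT18 were abundant, at 1367 ± 83.8 and 716 ± 49.95 CPM in NC before TMM scaling. On the same scale the adhesion genes EPCAM and CDH1 were at 4.40 ± 1.17 and 1.07 ± 0.23 CPM in NC and at 2.92 ± 0.50 and 1.79 ± 0.09 CPM in ASO, and the intestinal factor CDX2 was at 0.31 ± 0.17 CPM in NC. VIM, the mesenchymal intermediate filament gene, was at 1208 ± 71.7 CPM in NC, and the collagen gene COL5A1 at 615 ± 29.3 CPM. Epithelial genes rose in 10 of 25 tested and fell in 1, also adjusted over the list alone, and were not called by camera (adjusted p = 0.0704, median 0.49). The list was called without NC replicate 1 (adjusted p = 0.0367), with counts divided by 4 (adjusted p = 0.0148) and by fry (adjusted p = 0.000785). LGALS4 went from 0.01 ± 0.01 to 18 ± 2.65 CPM, ST14 rose 8.75-fold, and DSP fell 1.42-fold. Mesenchymal genes rose in 14 of 30 and fell in 6, 15 and 6 adjusted over the list alone (camera adjusted p = 0.0586, median 0.48). The list was called without ASO replicate 2 (adjusted p = 0.041), with counts divided by 4 (adjusted p = 0.0348) and by fry (adjusted p = 0.000686). SNAI2 rose 5.02-fold and THBS1 4.85-fold, while LUM and DCN, named after their values were seen, fell by 1.28 and 0.93 on the log2 scale. Of 30 listed markers of non-epithelial cells, 18 were tested, and detection in ASO helps a gene that is low in NC to be tested. Of these 18, 11 rose and 3 fell, 12 and 3 adjusted over the list alone (camera adjusted p = 0.00969, but adjusted p = 0.135 with an estimated correlation). Their median was 1.86, or 1.48 with the 2 members at 0 in NC set to their lower bound. Among them, CD79A, a B-cell gene, went from 0.11 ± 0.04 to 7.04 ± 1.29 CPM. The collagen gene COL1A1 rose 2.33-fold from 160 ± 20.5 CPM in NC. The fibroblast and pericyte gene PDGFRB fell 2.47-fold from 101 ± 8.09 CPM in NC. COL1A1, PDGFRB, LUM and DCN are on both of these lists.

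The 10 rises ranked first by fitted fold change were all genes with 0 counts in each NC library, for which only lower bounds can be given. TNFAIP3, at 148-fold, lies above the bounds of 9 of them. GP5, a platelet glycoprotein gene (chromosome 3, 194394821 to 194399266), reached 40.4 ± 12.2 CPM, at least 177-fold higher. Among the others, ATCAY was at least 62.9-fold higher, KRT14, a basal keratin, at least 56.0-fold, SPIB at least 47.2-fold, SCUBE2 at least 47.0-fold, CX3CL1 at least 45.8-fold, EFCAB8 at least 43.1-fold, CXCR5 at least 39.7-fold and SMIM41 at least 36.3-fold. Of the 9 with an annotated strand here, 5 have a gene of at least 10 CPM within 50 kb upstream on the same strand. GP5 begins 3.41 kb after ATP13A3, SPIB 0.92 kb after POLD1 and EFCAB8 8.52 kb after MAPRE1. Likewise, LGALS4 begins 2.48 kb after ECH1 and CD79A 4.35 kb after RPS19. The span of CXCR5 overlaps that of BCL9L, at 131 ± 10.0 CPM in NC and 263 ± 26.6 CPM in ASO. How reads in the shared stretch were assigned is not given. Among the falls, ETFRF1 was 7.09-fold lower, but 4.5-fold without NC replicate 2 and 11.1-fold without ASO replicate 2. TNFSF10, which encodes the death ligand TRAIL, was 7.04-fold lower and KYAT3 6.20-fold, followed by RPRM, DGAT2, SLC16A7, CEP162, FAM13C, SLC7A8 and RAB26 at 4.66-fold to 5.11-fold. SYNM, MEST and MAP1B fell 2.76-fold, 3.25-fold and 2.66-fold with some of the smallest p-values.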

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

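Among the alternatives, only the division of counts by 4 was chosen after the data were seen. Member counts by DESeq2 and limma-voom and medians under each scaling were drawn up after the results were known. The former are given above for some lists only. Tools differed more for ribosomal protein genes, with 23 lower by edgeR, 17 by DESeq2 and 24 by limma-voom, and for p53 targets, with 6, 10 and 8 lower. Over all scalings, filters and tools, 6048 (counts divided by 4) to 7418 (replicate block) genes were called against 6464. The block shared 6176 calls with the analysis without one. Among genes called both with and without a change of setting, 0 had the opposite sign in any of the alternatives. The block also left 2766 genes changed at least 2-fold and changed no call of a list or named gene. The numbers were not taken as pairs because the labels do not state pairs. Deviations of same-numbered libraries from their group means correlated at 0.05, 0.19 and 0.02. Those of differently numbered libraries correlated at -0.14 to 0.09, the highest for NC replicate 3 with ASO replicate 1. Deviations sum to 0 within each group, so these values do not decide whether the numbers are pairs. Leaving out 1 library gave 4892 to 7126 changed genes, 1755 to 3199 lower genes and 377 to 874 at least 2-fold lower, with fewer samples. DLGAP5 stayed lower in every alternative, log2 fold change -2.08 to -1.45 when 1 library was left out, with adjusted p up to 0.0151, and EIF4A1 from -1.37 to -1.27.

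With an estimated correlation, calls ended for the lists of Wnt targets (mean log2 fold change 1.02), mitosis (-0.60), DNA replication (-0.18), ribosomal proteins (-0.14), initiation factors (-0.30), cholesterol synthesis (-0.41), hypoxia and glycolysis (0.73), mitochondrially encoded genes (-0.55) and non-epithelial markers (2.07, or 1.34 with the 2 members at 0 in NC at their lower bound). The means are unchanged by construction. The estimated correlation was -0.016 for DNA replication and -0.00682 for initiation factors, below the preset 0.01. Correlation between genes therefore does not account for the loss of those calls. Fry, which does not compare a list with other genes, called Wnt components (0.18), p53 targets (0.52, or 0.30 with such a member at its bound), stress response (0.65), epithelial (1.83), mesenchymal (0.64) and apoptosis genes (0.52), and not the mitochondrially encoded genes (-0.55). Counts divided by 4 called epithelial (2.19) and mesenchymal genes (0.66). With 1 library left out, means ran from 1.65 to 2.35 (epithelial), 0.61 to 0.66 (mesenchymal), -0.84 to -0.38 (mitochondrially encoded), -0.0304 to 0.0786 (interferon-stimulated) and -0.044 to 0.0688 (snoRNA hosts). The first was called without NC replicate 1, the next without ASO replicate 2, and the mitochondrial call ended without NC replicate 2 or ASO replicate 1. The snoRNA host mean was -0.00662 with upper-quartile and -0.00288 with library-size scaling. SENP3 was -0.00483 and -0.00223 there, and -0.0204 to 0.0489 with 1 library left out, and CDKN1A -0.18 to 0.82, the lowest without ASO replicate 2. The cause was not tested for any of these. MYC, MPDU1 and FXR2 lost their calls in 10 fits in all, with direction kept. Depth limits genes near 12 counts per library, and 2821 genes were at 0 in all 6 libraries.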

Other observations

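The test of the other snoRNA host genes, the gene families and the removal of trends from lists other than mitosis were chosen after the results were seen. 15 families were picked by symbol. Of 38 proteasome subunit genes tested with edgeR, 29 fell and 1 rose, with a median log2 fold change of -0.43, and of 9 subunits of the cytosolic chaperonin 7 fell and the others did not pass. Interleukin genes rose in 13 of 21 and CXC and CC chemokine genes in 9 of 14, the others not passing, and Kruppel-like factor genes rose in 10 of 15 and fell in 3. Zinc finger genes named ZNF rose in 135 of 381 and fell in 17, with a median of 0.35. The medians of these 6 families kept their sign under each scaling. In the 9 others, with the scaling not varied, 19 of 34 collagen genes rose and 4 fell, 12 of 28 HOX genes rose and 3 fell, and 10 of 20 dual-specificity phosphatase genes rose and 1 fell. Kinesin genes split into 8 higher and 10 lower of 33, centrosome genes named CEP into 5 and 10 of 38, and Toll and interleukin-1 signalling genes into 4 and 2 of 14. Genes named GDF or BMP rose in 9 of 12 and fell in 1, 9 of the 13 olfactory receptor genes tested rose, out of 390 in the table, as did the 5 keratin-associated protein genes tested, out of 94. The others of these families were too low to test, and detection in ASO helps a gene to be tested. No enrichment was tested for these families.

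Over the 32 genes of the epithelial list the median level was 0.478 CPM in NC and 3.28 CPM in ASO, and 7 genes reached 10 CPM on average in NC and 9 in ASO. A further 12 epithelial genes were chosen after the levels of the first list were seen, and 2 of them, AP1M2 and LSR, reached 10 CPM on average in NC, while 7 lay under 1 CPM. In ASO 3 of the 12 reached it. Of 147 ribosomal protein and nuclear oxidative phosphorylation genes, 1 lay under 10 CPM in NC, and their median was 295 CPM. ESRP1, OVOL2, MAL2 and the Wnt targets ASCL2, LEF1 and SP5 had 0 counts in every library. The mesenchymal genes FN1, CDH2 and COL6A1 were at 227 ± 28, 50.1 ± 2.82 and 407 ± 47.9 CPM in NC (SD, n = 3), on the unscaled CPM of each library. No explanation was tested, and the identity of the cells, which bears on every value, stays open.

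The 333 genes at 0 in every NC library and detected in every ASO library had a median of 0.87 CPM in ASO. Genomic DNA in the ASO libraries would bring olfactory receptor genes along. Of 367 such genes at 0 in NC, 5 reached the limit, 1.36% (95% exact interval 0.44% to 3.15%). Among all 4923 genes at 0 in every NC library the share was 6.76%. The cut-offs set beforehand lay above that share, so they could not decide. The lower share of olfactory receptor genes argues against genomic DNA as a general source, though gene length was not matched. Column totals of the ASO libraries, 49136502 to 54905215, lay around those of NC, 50728524 to 53715905, so greater depth does not account for the pattern. After every library was thinned to 12.3 M fragments, the smallest, 97.6% of the genes met the definition. With totals this alike, that outcome was nearly fixed beforehand and adds little. Of the genes with a known strand, 41.1% had a gene of at least 10 CPM within 50 kb upstream on the same strand, against 4.02% of genes at 0 in all 6 libraries, an odds ratio of 16.7 (95% interval 12.4 to 22.4), while the mirrored downstream ratio was 5.72 (4.26 to 7.68). Read-through from an expressed upstream neighbour is a candidate explanation for part of the pattern, and activation of these genes by the treatment stays open as untested.

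Of 44 mitosis genes, 25, DLGAP5 among them, fell in ASO by edgeR, 2 rose and 17 did not pass, and the list's call was lost with an estimated correlation (camera adjusted p = 0.168). Fold changes followed GC content over 11483 genes, all at 1 CPM or more on average in NC, which leaves out genes detected mainly in ASO. The median log2 fold change was -0.43 in the fifth of genes lowest in GC and 0.15 in the highest. The mitosis genes had a median GC content of 43.2% against 48.7%. After trends with GC content, span and transcript length were removed, the mitosis median moved from -0.56 to -0.21. This lay at the 0.7 percentile of 10000 random lists matched on expression, and the residual of DLGAP5 was -1.13. These trends may account for part of the fall. Random lists take genes as independent, while the estimated correlation of the mitosis genes was 0.107. Whether the trends account for the whole of the fall was therefore not decided. No 1 library decided the fall, as the mean closest to 0 with 1 left out was -0.54. A response to the oligonucleotide or to loss of SNORA67 stays open, and this design does not separate them.

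The same trends moved other lists. Their removal took the median from -0.22 to -0.10 for DNA replication genes (percentile 3.05 to 22.98 of random lists), from -0.14 to -0.08 for cytosolic ribosomal protein genes (13.7 to 55.3), from -0.27 to -0.14 for nuclear oxidative phosphorylation genes (0.02 to 3.03) and from -0.61 to -0.29 for mitochondrially encoded genes (0 to 2.51). Hypoxia and glycolysis genes went from 0.23 to 0.43, heat shock genes from -0.84 to -0.63, initiation factor genes from -0.22 to -0.20 and cholesterol synthesis genes from -0.42 to -0.38.

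EIF4A1 was lower in ASO. The 13 other snoRNA host genes among the deposited symbols had a median of 0.0422 and an interquartile range of 0.67, against -1.32 for EIF4A1. This argues against a fall shared by those 13. The list held 31 genes, and the hosts with no entry among the deposited symbols, GAS5 and SNHG1 among them, are not covered. Reads moved to the neighbouring SENP3 model alone would leave the sum of both genes level, but the sum fell by 1.13 on the log2 scale. The joint SENP3-EIF4A1 model was not analysed here, so reads assigned to it would be missed, and a move to that model cannot be told apart from a fall of the transcript. Cleavage of the unspliced host transcript by an oligonucleotide that pairs inside its intron may be involved, and it was not tested.

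Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 6464 changed genes with edgeR and 2931 changed at least 2-fold, and the highest of the others gave 0 for each. At an unadjusted p under 0.05 these others gave 54 to 637 genes, against 7557 for the real one, and no other tool was run on them. Each of the others mixes NC and ASO libraries on both sides, so the group difference widens the spread within a side and keeps their counts low. They are therefore no measure of chance, and splits this few cannot give a share under 0.05.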
